A study of Macaca mulatta with 6 samples.

How the data were processed

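Polyadenylated RNA of 3 control libraries (50% heat-inactivated human serum) and 3 normal serum libraries (50%, 4 hours) was sequenced, and the labels gave each library its treatment and replicate number. Per the submitters' processing notes, TopHat2 2.0.7, Cufflinks 2.1.1 and Cuffdiff 2.1.1 were used, and the genome build is not given in the sources used here. The deposited table holds FPKM per transcript for each library, as the authors computed it. It also holds the authors' FPKM per treatment, which equals the mean of the 3 libraries within 0.1% for 99.2% of transcripts, and the authors' log2 fold change, p-value and q-value per transcript. The authors' marks of passing correspond to a log2 change of at least 1.00 in size and q-values up to 9.97e-04.

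The table has 44605 transcripts, 37.0% of them at 0 in all libraries. Values of transcripts with the same gene symbol were summed, giving 24932 genes. Of 7008 gene identifiers without a symbol, 256 received one from a table of gene names. Isoforms, near-identical copies and overlapping genes are thus not told apart, and the library kit as named does not establish strand. Very short transcripts gave erratic values, such as 142052 FPKM for a transcript of 101 bases (MIR1282) in 1 library and 0 in the other 5.

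Since the values are FPKM and not counts, log2(FPKM + 1) of genes with a mean of at least 1 FPKM was tested with limma 3.58.1 in R 4.3.3, with a trended empirical Bayes variance and Benjamini-Hochberg adjustment. Fold changes on this scale understate those of low genes. Folds in the text are ratios of mean FPKM. Errors are SD over 3 libraries. Gene lists, fixed before the data were examined, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists with at least 5 measured members out of 28. An alternative estimated the inter-gene correlation from the libraries themselves. With so few libraries it has little power, so a call lost there does not decide against a list. Of 712 list members 666 were found in the table by symbol. The genes named were the 10 largest rises and 10 largest falls among called genes with a symbol and separate groups, up to 4 members of each list with the smallest adjusted p (or the 2 highest where none passed), and a fixed set of complement, protease, adhesion and cytokine genes, and any other is marked as chosen after its values were seen. A few genes that meet this rule are not reported here.

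Depth was read from transcripts of single-transcript genes at the lowest values, where 1 fragment is worth an amount set by transcript length. Within 0.1 fragments, 100% of low values were whole in replicates 2 and 3 of both treatments, against 46.3% and 42.5% in the replicate 1 libraries and 20% by chance. A transcript of 1000 bases gains between 0.0690 and 0.0841 FPKM per fragment in replicates 2 and 3. The gene test has no batch term, and the replicate 1 libraries were given a term or left out only in alternatives.

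The gene test was tested on 5 simulated data sets of 11818 genes with the means and spreads of these libraries and 200 genes changed. It recovered 18.4% of genes changed 1.25-fold, 66.8% at 1.5-fold, 91.6% at 2-fold and 98.4% at 4-fold, and 5.51% of its calls were false. Far more genes, 6381, were called in the data, and recovery depends on the share of genes changed. The changed genes were also drawn without those at low levels. These values thus hold for the simulated setting only. Alternatives varied the pseudocount, the filter, the scaling, the variance model, the summing of transcripts and the libraries included. Batch, short-transcript and length-trend alternatives were chosen after seeing the data.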

Results

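RNA was measured in RF/6A cells, a rhesus macaque line described as chorioretinal endothelial, after 4 hours in 50% human serum. The marker genes given below do not establish that identity. The control cells received serum whose complement had been destroyed by heating, and the treated cells received normal serum, in which active complement can assemble the membrane attack complex, a pore that inserts into cell membranes. The comparison asks how the transcripts of these cells differ between normal and heat-inactivated serum. No sample had complement removed or blocked in another way. Active complement thus cannot be told apart from anything else in serum that heating changes, nor the pore from other products of complement. There were 3 libraries per treatment, 6 in all, made from polyadenylated RNA of cells grown on porous culture inserts. Nothing in the labels says whether the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. The values are FPKM, fragment numbers scaled for transcript length and for the depth of the library. In replicates 2 and 3 the lowest values were whole multiples of what 1 fragment is worth, which placed the depth of those 4 libraries between 14700000 and 17900000 fragments after the authors' scaling. The replicate 1 libraries of both treatments did not follow this rule, and their depths, read the same way as 15900000 and 14300000 fragments, are approximate. Between 11589 and 11837 genes per library reached 1 FPKM.

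The libraries separated by treatment. The first principal component of log2(FPKM + 1) held 61.1% of the variance and placed all control libraries on one side and all normal serum libraries on the other. Pearson correlations across genes lay between 0.977 and 0.984 within a treatment and between 0.934 and 0.949 across treatments. The next component, with 13.2% of the variance, set the replicate 1 libraries of both treatments (17.6 in the control and 24.2 in normal serum) apart from the other 4 (-13.7 to -7.00).

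Normal serum changed the transcripts of 6381 of the 11818 genes tested (limma, adjusted p under 0.05), of which 3291 were higher and 3090 lower. The change was at least 2-fold on the log2(FPKM + 1) scale for 713 genes, 410 higher and 303 lower. Among the largest rises, PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, went from 2.44 ± 0.187 to 91.1 ± 2.54 FPKM (SD, n = 3 per treatment), FGF1, a fibroblast growth factor, from 2.03 ± 0.322 to 66.3 ± 19.7 FPKM, and SEMA7A, a membrane-anchored semaphorin, from 15.7 ± 3.00 to 251 ± 11.1 FPKM. Part of the FGF1 value in normal serum came from a transcript under 300 bases, listed at 0 in the control. Without it FGF1 stood at 38.3 ± 5.88 FPKM there, and its log2 change was 3.69 instead of 4.44. The orphan nuclear receptors NR4A1 and NR4A2 rose 23.5-fold and 26.4-fold in mean FPKM, and AREGB, the table's name for an amphiregulin gene, rose 34.5-fold. WNT1, a secreted signalling protein, stood at 19.7 ± 2.12 FPKM in normal serum and at 0.0742 ± 0.0778 FPKM in the control, about the value of 1 fragment. The small nucleolar RNAs SNORA3, SNORA24 and SNORA8 also met the rule for naming, but each name sums several short loci, and SNORA3 and SNORA24 were listed at 0 in the control libraries. SNORA3 was no longer called when the highest transcript stood for the gene (adjusted p = 0.0648), and SNORA8 with robust variance estimation (adjusted p = 0.0788), or without heat-inactivated serum replicate 2 (adjusted p = 0.0573) or replicate 3 (adjusted p = 0.0569), or without normal serum replicate 2 (adjusted p = 0.0515) or replicate 3 (adjusted p = 0.0507).

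The largest falls were in CCL11, an eosinophil-attracting chemokine (16.9 ± 2.33 to 0.414 ± 0.435 FPKM), and TXNIP, the thioredoxin-interacting protein (262 ± 17.4 to 23.7 ± 6.17 FPKM). The chemokine CXCL1 went from 373 ± 21.3 to 53.8 ± 9.64 FPKM, and DCN, which encodes the matrix proteoglycan decorin, from 828 ± 33.2 to 158 ± 11.7 FPKM. PLSCR4, ADAMTS9, C1QTNF7, CYP1B1, IL1B and INHBE completed the 10 largest falls, with log2 changes between -2.65 and -2.19. Within replicates 2 and 3 alone, 5462 genes were called, and with a term for the replicate 1 libraries 7063 were. The replicate 1 libraries by themselves number 1 per treatment, too few for a test. When the libraries were rescaled to the same total FPKM, the median log2 change of all genes moved from 0.01 to -0.12 and the calls from 51.6% higher to 34.6% higher, so small changes depend on the scaling. Heat-inactivated serum replicate 3 totalled 1007950 FPKM, of which 142052 came from a MIR1282 transcript listed at 0 in the other libraries. The other control libraries totalled 852828 and 867794 FPKM. The normal serum libraries totalled between 980877 and 1016470 FPKM. That 1 very short transcript thus brought the total of heat-inactivated serum replicate 3 nearer to theirs. Rescaling without it, which was not run, would lower the log2 changes further. It therefore does not account for the lower changes after rescaling, here and below.

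**Figure D1:**
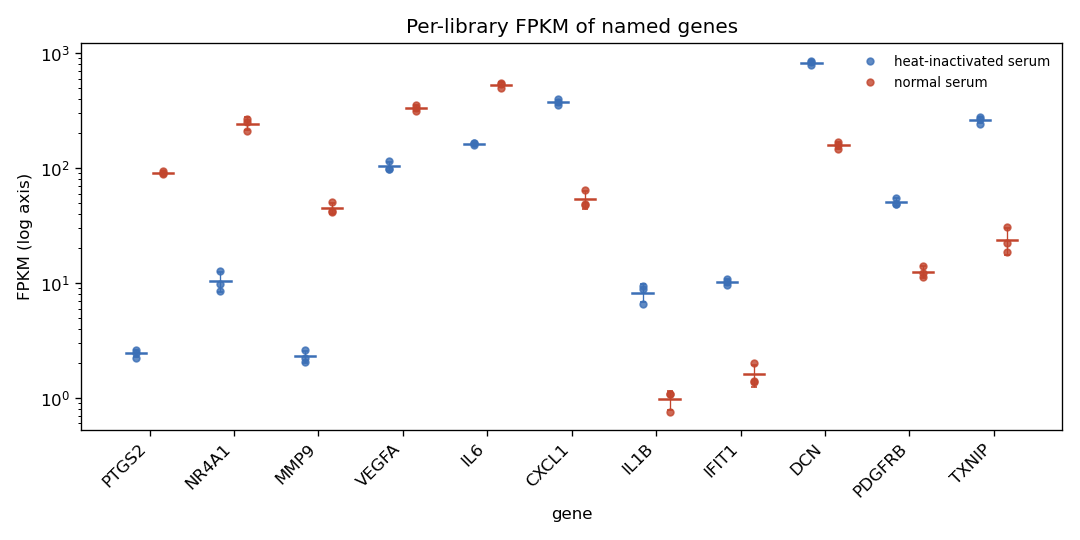
FPKM on a log axis of some of the named genes in each library, with 3 heat-inactivated serum libraries in blue and 3 normal serum libraries in red. Points are libraries, horizontal lines are means and bars are SD, and the treatments do not overlap for any gene shown, as for PTGS2 with means of 2.44 and 91.1 FPKM.

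Immediate early genes, which respond first to many stimuli, were called higher than other genes by camera (adjusted p = 7.45e-08), but not with an estimated correlation (adjusted p = 0.294). Of 29 measured members 22 were higher, 0 lower and 7 not past the threshold, with the same counts when adjusted over the list alone. DUSP5, a phosphatase that acts on ERK kinases, went from 12.3 ± 1.01 to 180 ± 7.13 FPKM, and NR4A3 from 0.893 ± 0.159 to 14.2 ± 0.326 FPKM. EGR1 was not past the threshold, at 313 ± 42.7 and 302 ± 53.7 FPKM, and neither was JUN, named after its values were seen, at 169 ± 11.6 and 168 ± 17.9 FPKM. FOS was not analysed here.

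Cytokines and chemokines moved in both directions. Of 19 measured members 8 were higher and 9 lower, or 9 and 9 when adjusted over the list alone. IL6 rose 3.26-fold (163 ± 3.39 to 531 ± 27.7 FPKM), the monocyte chemoattractant CCL7 4.53-fold and TGFB1 2.18-fold, while IL1B fell from 8.27 ± 1.49 to 0.971 ± 0.189 FPKM. IL8, the neutrophil chemokine CXCL8, and CCL2 were already abundant in the control (997 ± 20.3 and 2001 ± 171 FPKM) and were higher by 0.24 and 0.33 on the log2 scale, calls that ended with rescaling to the same total FPKM (adjusted p = 0.437 and 0.209) and with quantile normalization (adjusted p = 0.428 and 0.112), where the IL8 change was -0.0683. The IL8 call also ended when the highest transcript stood for the gene (adjusted p = 0.397) and when any library but normal serum replicate 1 was left out (adjusted p from 0.0525 to 0.0781). The list as a whole was not called (adjusted p = 0.676). Among targets and feedback genes of NF-kappaB, the transcription factor of inflammatory signalling, 13 of 18 were higher and 4 lower, the same as when adjusted over the list alone. TNFAIP3, an NF-kappaB inhibitor, rose 2.28-fold, NFKBIB 2.24-fold and NFKB1 2.02-fold. NFKBIA, another inhibitor and named after its values were seen, fell from 131 ± 0.279 to 84.0 ± 12.3 FPKM. The list was called higher (adjusted p = 0.00415), but not with an estimated correlation (adjusted p = 0.294).

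Matrix proteases were called higher (adjusted p = 0.0355) and structural matrix genes lower (adjusted p = 0.00869), neither with an estimated correlation (adjusted p = 0.405 for both). Of 27 matrix proteases and inhibitors 14 were higher and 6 lower, and of 26 structural genes 5 were higher and 14 lower, with the same counts when adjusted over each list alone. MMP9, a gelatinase, went from 2.30 ± 0.291 to 44.9 ± 4.95 FPKM, and MMP3, a stromelysin, from 0.369 ± 0.0978 to 9.16 ± 1.54 FPKM. ADAMTS1 rose 5.29-fold and ADAMTS9 fell by 2.33 on the log2 scale. The collagen genes COL1A1 (3870 ± 236 to 2026 ± 92.8 FPKM) and COL3A1 (1888 ± 100.2 to 795 ± 75.0 FPKM) fell, as did the fibrillin gene FBN1 and the laminin gene LAMB1. COL1A1 and COL3A1 are also mural and fibroblast markers, a list with 8 of 12 lower, so the lists overlap in these genes. FN1 was listed at 0 in all libraries, with the authors' deposited table giving its status as too many fragments to estimate. The call of the proteases also ended with a mean of at least 5 FPKM (adjusted p = 0.173) and with quantile normalization (adjusted p = 0.0878). The call of the structural genes also ended when the trend with transcript length was removed (adjusted p = 0.0507).

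Angiogenic ligands and receptors were largely higher, 16 of 26 against 4 lower, also when adjusted over the list alone. VEGFA, the main vascular growth factor, rose 3.22-fold (104 ± 9.74 to 334 ± 18.9 FPKM), ANGPTL4 9.94-fold, HBEGF 6.95-fold and EDN1, the precursor of a vasoconstrictor peptide, 7.21-fold. THBS1, which inhibits angiogenesis, rose 3.49-fold. The list was called (adjusted p = 0.00415), but not with an estimated correlation (adjusted p = 0.294). Of 20 endothelial adhesion and junction genes 11 were higher and 6 lower, likewise when adjusted over the list alone. ICAM1, a leukocyte adhesion receptor, rose 1.64-fold, the integrin genes ITGA2 and ITGA5 3.95-fold and 2.44-fold, and CDH2 2.52-fold. SELE, the endothelial selectin, was near 0 in both treatments (0.0179 ± 0.0310 FPKM in the control and listed at 0 in normal serum). This list was called (adjusted p = 0.0359), but not with an estimated correlation (adjusted p = 0.405), with a term for the replicate 1 libraries (adjusted p = 0.0587) or for each replicate number (adjusted p = 0.0571), without normal serum replicate 3 (adjusted p = 0.0509), with a mean of at least 5 FPKM (adjusted p = 0.116) or with quantile normalization (adjusted p = 0.0778).

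Complement genes were mixed, with 4 of 13 higher and 7 lower, also when adjusted over the list alone. Of all genes tested 54.0% were called. The list was not called by camera (adjusted p = 0.26). It was called lower by fry (adjusted p = 6.14e-04), which does not compare a list with other genes. C1R, C1S and C2, which encode proteases of the classical pathway, fell to 0.609, 0.536 and 0.527 of their control means, while C1QBP, which encodes a protein that binds C1q, rose 1.79-fold (203 ± 12.7 to 363 ± 10.9 FPKM). Of the membrane regulators that protect cells from complement, CD46 fell from 22.0 ± 1.47 to 16.2 ± 1.36 FPKM and CD55 rose from 19.8 ± 1.92 to 24.1 ± 1.87 FPKM. CD59, which blocks the membrane attack complex, stood at 99.7 ± 4.83 and 103.2 ± 6.09 FPKM (adjusted p = 0.57). The CD55 call ended within replicates 2 and 3 alone (adjusted p = 0.0559) and when replicate 1 (adjusted p = 0.0916) or 2 (adjusted p = 0.113) of heat-inactivated serum or replicate 2 (adjusted p = 0.102) or 3 (adjusted p = 0.106) of normal serum was left out. It ended too with rescaling to the same total FPKM (log2 0.28 to 0.14, adjusted p = 0.274), with quantile normalization (adjusted p = 0.0776), when genes under 1 FPKM were kept (adjusted p = 0.0531) and with the length trend removed (adjusted p = 0.0523). C3 was not analysed here. Among 15 genes associated with macular degeneration, which share members with other lists, 4 were higher and 7 lower, also when adjusted over the list alone (adjusted p = 0.499 for the list). Its median was -0.23 and its mean 0.07, so the summaries differed in sign.

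Interferon-stimulated genes were called lower (adjusted p = 0.00415), but not with an estimated correlation (adjusted p = 0.405). Of 20 measured members 12 were lower and 1 higher, or 13 and 1 when adjusted over the list alone. IFIT1 went from 10.3 ± 0.605 to 1.60 ± 0.352 FPKM, MX1 from 10.7 ± 0.177 to 1.91 ± 0.443 FPKM, and IFIT2 and STAT2 fell by 1.67 and 1.17 on the log2 scale.

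Of the stress lists, heat shock genes and p53 and apoptosis genes were called higher (adjusted p = 0.00319 and 0.0419), but not with an estimated correlation (adjusted p = 0.405 for both). Of 17 heat shock genes 13 were higher and 1 lower, with HSPB8 rising 2.50-fold, FKBP4 1.75-fold and HSPE1 1.60-fold, and of 23 p53 and apoptosis genes 12 were higher and 3 lower, with CDKN1A, a cyclin-dependent kinase inhibitor, rising 2.65-fold and PMAIP1, a death-promoting BCL2 relative, 3.74-fold. Adjusted over the list alone the heat shock counts did not change and the apoptosis list had 13 higher. The apoptosis call also ended without normal serum replicate 3 (adjusted p = 0.0509), with a mean of at least 5 FPKM (adjusted p = 0.116) and with the length trend removed (adjusted p = 0.0758). The unfolded protein list (10 of 26 higher, 4 lower, adjusted p = 0.248), the NRF2 list (8 of 16 higher, 2 lower, adjusted p = 0.0772) and the plasma membrane repair list (10 of 25 higher, 8 lower, adjusted p = 0.617) were not called, and adjusting over each list alone left these counts as they were. The NRF2 list was called when genes under 1 FPKM were kept (adjusted p = 0.0395). Each list held changes both ways. MANF of the unfolded protein list rose 1.90-fold and CHAC1 fell by 0.76 on the log2 scale, as did another of its 4 members with the smallest adjusted p. PRDX1 of the NRF2 list rose 1.77-fold and SQSTM1 fell by 0.46, and in the repair list S100A11 rose 1.79-fold and the ferlin gene MYOF fell by 0.73.

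Actin and SRF target genes were called higher (13 of 23, 3 lower, adjusted p = 0.0355), and so were oxidative phosphorylation genes (11 of 20, 1 lower, adjusted p = 0.0355), which had 12 higher when adjusted over the list alone. Neither was called with an estimated correlation (adjusted p = 0.405 and 0.471). Both calls ended after quantile normalization (adjusted p = 0.624 and 0.984) and with a mean of at least 5 FPKM (adjusted p = 0.116 for both), and the oxidative phosphorylation call also with rescaling to the same total FPKM (adjusted p = 0.124) and with the length trend removed (adjusted p = 0.0888). TAGLN2 and FHL2 rose 2.69-fold and 2.74-fold, while ACTA2, smooth muscle actin, fell from 22.1 ± 0.962 to 6.77 ± 0.375 FPKM. The actin call also ended without heat-inactivated serum replicate 1 (adjusted p = 0.0567). Of 26 ribosomal protein genes, RPSA alone was past the threshold (higher, 0 when adjusted over the list alone) and the list was not called (adjusted p = 0.621). Cell cycle genes (16 of 35 higher, 3 lower, adjusted p = 0.0681), hypoxia and glycolysis genes (11 of 23 higher, 5 lower, adjusted p = 0.0672), cholesterol genes (3 of 21 higher, 7 lower, adjusted p = 0.126) and metallothioneins with zinc transporters (2 of 7 higher, 3 lower, adjusted p = 0.541) were not called. Adjusted over the list alone, the cholesterol list had 2 higher and the other 3 lists kept their numbers. HK2, a hexokinase, rose 4.26-fold and CCND1, cyclin D1, 2.06-fold, and MT1E fell from 296 ± 36.7 to 137 ± 23.3 FPKM while the zinc transporter gene SLC39A10 rose by 0.97 on the log2 scale. The cell cycle list was called without heat-inactivated serum replicate 2 (adjusted p = 0.0213) or normal serum replicate 3 (adjusted p = 0.0232), and the hypoxia list without heat-inactivated serum replicate 3 (adjusted p = 0.0308). Both were called when genes under 1 FPKM were kept (adjusted p = 0.0385 and 0.0286).

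Of 21 endothelial identity markers found, 6 reached a mean of 1 FPKM, 5 of which were higher in normal serum and 0 lower, among them PECAM1 (3.35 ± 0.288 to 7.95 ± 0.634 FPKM), ESAM, FLI1 and ENG. The ENG call ended within replicates 2 and 3 alone (adjusted p = 0.0619), without normal serum replicate 2 (adjusted p = 0.0515), with rescaling to the same total FPKM (log2 0.27 to 0.13, adjusted p = 0.325) and with quantile normalization (log2 0.0799, adjusted p = 0.336). Other markers, named after their values were seen, had a mean below 1 FPKM. CDH5, VE-cadherin, was listed at 0 in the control libraries and at 0.0110 ± 0.00974 FPKM in normal serum. KDR (0.370 in the control and 0.105 in normal serum), TEK (0.0930 and 0.0457), TIE1 (0.0177 and 0.0115) and CLDN5 (0.233 and 0.255) were also low in both. VWF went from 0.172 to 1.05 FPKM. The list was called higher (adjusted p = 0.0355), but not with an estimated correlation (adjusted p = 0.312), with a mean of at least 5 FPKM (adjusted p = 0.116) or when genes under 1 FPKM were kept (adjusted p = 0.151). Mural and fibroblast markers were lower in 8 of 12 and higher in 2, with PDGFRB going from 50.8 ± 3.65 to 12.6 ± 1.47 FPKM and CSPG4 from 14.5 ± 0.222 to 40.9 ± 0.273 FPKM. That list was called lower (adjusted p = 0.00869), but not with an estimated correlation (adjusted p = 0.312) or when genes under 1 FPKM were kept (adjusted p = 0.0727). Both lists had the same counts when adjusted over the list alone. Of 19 mural and fibroblast markers found 12 reached a mean of 1 FPKM, against 6 of 21 endothelial ones. In the control COL1A1 stood at 3870 and DCN at 828 FPKM, and the endothelial marker ENG at 61.2 FPKM. With CDH5, KDR, TEK, TIE1 and CLDN5 below 1 FPKM, these levels do not establish the cells as endothelial. The markers of other cells listed at 1 FPKM or more were 2 retinal pigment epithelium markers (SERPINF1 lower), 2 neural retina markers (SNAP25 higher), 3 epithelial markers (CDH1 lower, CLDN4 and KRT7 higher) and 3 blood cell markers (LYZ lower), too few for a list test. Several others, such as OTX2, RGR and ARR3, were listed at 0 in all libraries, but so were TPI1 and TXNRD1, which most cells use, so a value of 0 here need not mean that a gene is silent. The KRT7 and LYZ calls each ended in 4 of the 6 tests that left 1 library out (KRT7 without heat-inactivated serum replicate 1 or 2 or normal serum replicate 2 or 3, adjusted p from 0.0593 to 0.108, and LYZ without heat-inactivated serum replicate 1 or 3 or normal serum replicate 2 or 3, adjusted p from 0.0922 to 0.104). Both also ended with quantile normalization (adjusted p = 0.0556 and 0.0692) and when genes under 1 FPKM were kept (adjusted p = 0.0565 and 0.0611), and the KRT7 call with rescaling to the same total FPKM (adjusted p = 0.246) and when the highest transcript stood for the gene (adjusted p = 0.536). Adjusted over the list alone, both neural retina markers were higher and the others did not change.

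**Figure D2:**
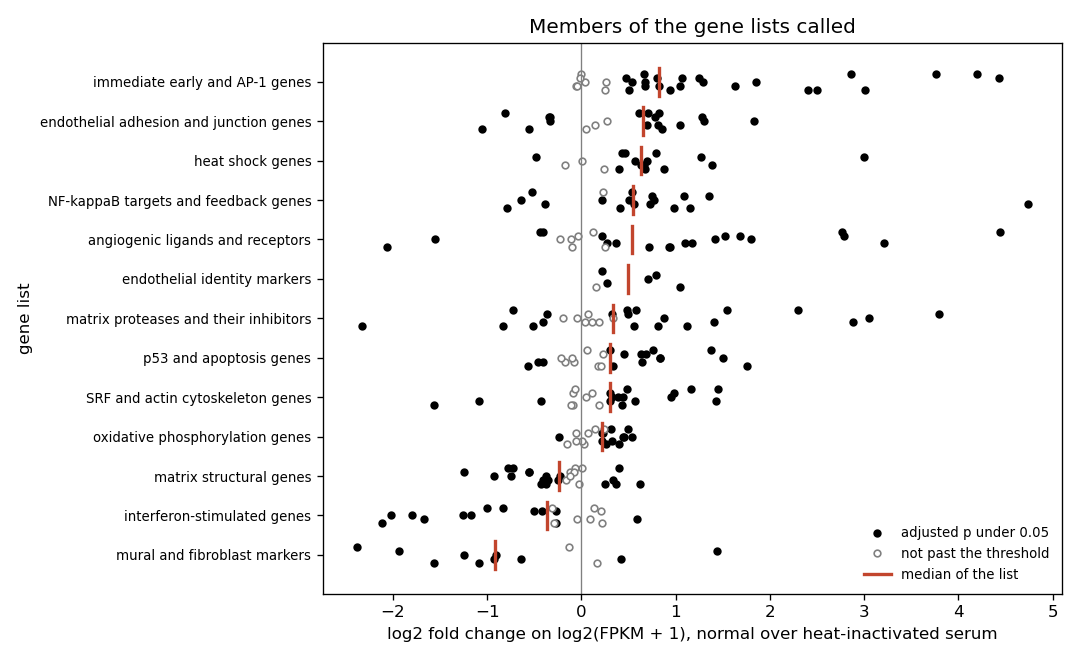
Log2 fold change on log2(FPKM + 1), normal over heat-inactivated serum, of each measured member of the 13 gene lists called. Filled points passed the adjusted threshold, open points did not, red lines are list medians, and the medians run from -0.92 for mural and fibroblast markers to 0.83 for immediate early genes.

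The authors' deposited table marks 1143 transcripts as passing its 3 thresholds, 541 higher and 602 lower in normal serum. In the authors' deposited table these belong to 1070 genes, of which 1041 were among the genes tested here. Of those, 1022 were past the threshold here and 1021 in the direction of the authors' deposited table. Both sets of calls come from the same libraries, so this overlap is no independent check.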

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

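Tests confined to replicates 2 and 3, a term for the replicate 1 libraries, transcripts of at least 300 bases and removal of the length trend were chosen after seeing the data. The number of genes changed stayed within 1.5 times of 6381 under every alternative run except the added requirement of a 2-fold change (713 genes, which is a stricter rule). It ranged from 5465 to 5853 when 1 library was left out. The number of gene lists called was 13. It was 7 with a mean of at least 5 FPKM, where fewer genes are tested, and 0 with an estimated correlation, where the smallest adjusted p was 0.294 and 3 lists had an unadjusted p under 0.05. The angiogenic and endothelial identity lists lost their calls there although their estimated correlations (-0.0292 and -0.126) were below the preset 0.01. A lost call there thus need not come from correlation between genes. The number of lists called was 17 with fry, which does not compare a list with other genes, and 12 to 14 when 1 library was left out. Beyond those called by camera, fry called the complement list lower (adjusted p = 6.14e-04). It also called the unfolded protein, NRF2 and hypoxia lists higher (adjusted p = 0.00308, 0.00920 and 0.00543). Of the 117 named genes 115 were called, and 109 to 115 when 1 library was left out.

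Same-numbered libraries deviated together for number 1 (r = 0.19) but hardly for numbers 2 and 3 (r = 0.03 and 0.01). With 3 libraries per treatment this does not settle whether the numbers pair the samples. With the replicate block 6775 genes, 12 lists and 115 named genes were called, the adhesion list being lost (adjusted p = 0.0571).

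Directions reversed in few cases, and the cause was not tested. The median of the cytokine list was 0.24 with a mean of at least 5 FPKM, and fry gave it the opposite direction to camera (median -0.48), as for the macular degeneration list (median -0.23). The ribosomal list turned to -0.11 when rescaled to the same total, -0.13 with quantile normalization and -0.0225 with the length trend removed, and the membrane repair list to -0.0576 with quantile normalization. With the latter the median of the oxidative phosphorylation list, called in the main test, also went from 0.22 to -0.0245, though camera kept its direction. SREBF2 was 1.27 with the highest transcript per gene. CD59 was -0.0947 when rescaled and -0.15 with quantile normalization, and IL8 was -0.0683 with the latter. EGR1, not called, was 0.20 within replicates 2 and 3, and ranged from -0.155 (without heat-inactivated serum replicate 3) to 0.0985 (without normal serum replicate 1) when 1 library was left out. Tests that need counts were not run because the values are FPKM. Depth limits genes near the value of 1 fragment, such as WNT1 in the control.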

Other observations

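The tests of the replicate 1 libraries, of fragment length and of the families with the length trend removed were chosen after the result was seen, as were the gene families below. Transcripts of proteasome subunits, which form the cell's main protein-degrading complex, were higher in normal serum in 30 of 44 genes and lower in 2, with a median log2 change of 0.34. Those of mitochondrial ribosomal proteins were higher in 44 of 68 and lower in 1, with a median of 0.34. When rescaled to the same total FPKM the medians were 0.20 and 0.20, with 18 and 23 genes higher, and neither median changed sign under any scaling run. Of 13 protein genes encoded in the mitochondrial genome 8 were higher and 0 lower (median 0.47), a count that fell to 3 without normal serum replicate 1, to 4 without heat-inactivated serum replicate 3 and to 5 without heat-inactivated serum replicate 2, and rose to 11 without heat-inactivated serum replicate 1. It was 3 when rescaled to the same total FPKM (median 0.33), 4 with quantile normalization (median 0.27), 5 with the length trend removed (median 0.42) or when genes under 1 FPKM were kept, 11 with a mean of at least 5 FPKM, and 12 with a term for each replicate number or for the replicate 1 libraries, with 0 lower in each.

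Both families have short transcripts, with a median longest transcript of 1236 and 881 bases. The trend with length is argued against as the whole cause of their rise, since it was small at these lengths. The median log2 change of all genes was 0.07 from 500 to 1000 bases and 0.03 from 1000 to 2000 bases. What remains after its removal may be overstated, because the families were picked for being high. With it removed from each library, the level of the proteasome family relative to all genes was still higher in normal serum by 0.328 (SE 0.0397 over the libraries, 0.352 before removal) and that of the mitochondrial ribosomal family by 0.288 (SE 0.0318, 0.339 before). Random lists matched on length and mean level had typical medians of 0.18 and 0.18, and the proteasome median lay at percentile 98.78 and the mitochondrial ribosomal median at percentile 99.56 of 10000 such lists. A percentile this high was set beforehand to count against short length, but the families were picked because they were high, which by itself places them near the top, so that test does not decide. A share of the rise from length together with mean level, and a response to active complement, stay open.

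Fold changes fell with transcript length, from a median log2 of 0.12 below 500 bases to -0.16 from 5000 bases on. A different mean fragment length between treatments is argued against, since the slope was still -0.0874 per doubling (SE 0.0137) among genes of at least 2000 bases, where fragment length hardly matters. The trend is also argued against as the whole cause of the calls. Of the 6381 genes called, 5979 stayed past the threshold in the same direction once it was removed. Of the genes changed at least 2-fold 99.7% did, the share set beforehand as the test. A trend of this size could hardly undo changes that large, so that share does not decide. RNA integrity or size selection that differed with the treatment cannot be told apart from the treatment itself, because the slopes of the treatments did not overlap (mean difference -0.0484) and integrity was not measured in these data.

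In the replicate 1 libraries of both treatments low values were not whole multiples of 1 fragment. Lower depth stays open, and the depths read for these libraries, which are approximate, differ in what they show. That of the control library (15900000 fragments) lay above those of heat-inactivated serum replicate 3 (14700000) and normal serum replicate 2 (15100000). Low values were 100% whole in both of the latter. That of the normal serum library (14300000) was the lowest of all. Of the other 4 libraries 1 listed fewer transcripts above 0 (22679) than both of these (22997 and 22872), while the other 3 listed more (23182, 23180 and 23710). The 1 library was first taken to count against lower depth. After the value was known at least 2 were required, since 1 library decides little, and the explanation is open only under that changed rule. Different preparation or processing may account for it, as the offsets of these libraries from their other replicates correlated across genes between the treatments (r = 0.24, genes not being independent, against 0.05 and 0.02 for replicates 2 and 3). No biological explanation was tested.

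Of the 10 splits of the 6 libraries, 1 (the treatments) called 6381 genes and the highest other called 2. With 10 splits no share under 0.05 can be had.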
